A study of Drosophila melanogaster with 4 samples.

How the data were processed

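The data are chromatin immunoprecipitation followed by sequencing (ChIP-seq) for histone H3 trimethylated at lysine 9 (H3K9me3) in wild-type Oregon-R embryos of Drosophila melanogaster, staged at 14 to 16 h. Chromatin was crosslinked with 1.8% formaldehyde, per the labels' protocols. The labels name 2 ChIP libraries and 2 input libraries, 1 input for each ChIP library. Each ChIP library came with 1 list of enriched clusters, and a further list covers the series. No values of the input libraries were used here.

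Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes, and positions are on FlyBase release 5, per the file headers. The lists hold regions of significant enrichment as the authors called them. The caller, its threshold and the filters on reads are not given in the sources used here. For each cluster the authors deposited a start, an end and a score. The score is above 0 in every cluster, and its scale is not stated. It was therefore used only to describe, rank or filter clusters within a list, and to rank paired clusters of both libraries; medians of the score are also given as a mean over the libraries, which takes both lists to be on the same scale. There is 1 list per ChIP library. The series-wide list is labelled as the set of replicates, and how reads or calls were combined for it is not stated. Its shortest cluster is 1001 bp long and that of each per-library list is 1301 bp, so the minimum length may have differed between them. No read counts came with the lists, so the depth per library is unknown. Confidence intervals on shares of clusters are exact Clopper-Pearson intervals at 95%, and cover counting error only.

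All other values were computed here in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1. The covered share of a sequence is the percentage of its bases, by the length in the file headers, that lie in clusters. A cluster running past a sequence end (2 in replicate 1, 4 in replicate 2 and 4 in the series-wide list, by at most 926 bp) was cut at that end, and 1 cluster each in replicate 2 and the series-wide list that starts at 0 was cut at the first base. The lengths may include unsequenced gaps, which were not measured. Of the 14 sequences in the headers, 13 hold clusters; the remaining one, of unplaced extra sequence (Uextra), holds 0 and was left out of all shares. Means ± SD are over the 2 ChIP libraries. The labels do not say whether these came from separate embryo collections, so the SD may be technical.

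Overlap of the libraries was measured as the Jaccard index of covered bases and as the share of clusters that overlap the other list by at least 1 bp. It was tested against 1000 circular shifts of 1 list within each sequence, one-sided, where the smallest p is 0.001. The centromere-proximal 1 Mb of arms 2L, 3L and X lies at the high end of the coordinates and that of 2R and 3R at the low end. Its covered share was set against the rest of the arm by an exact two-sided permutation test over the 5 arms (smallest p 0.063), and per arm by 1000 circular shifts with Benjamini-Hochberg adjustment over the 5 arms. A cluster was put in a class by its midpoint. Scores of both libraries were ranked against each other over clusters that overlap one to one, with 1000 bootstrap resamples for the interval of rho; clusters are not independent replicates.

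The functions were tested on simulated data. With 51.1% of 1757 arm and chromosome 4 clusters kept in a second list, 51.1% were recovered as overlapping. Of 60 copies of the list, each shifted by a random distance within every sequence, 2 had a shift p at or below 0.05. Both simulations check the arithmetic only, since the second lists were a subset or shifted copies of the first.

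The design, the alternatives and the rule for named regions were fixed before the data were examined, apart from the alternatives for the density of clusters on X and for folds between parts of the genome, which were added later. The rule names the longest region covered in both libraries on each of the 5 arms and chromosome 4, the 3 longest on each arm outside the proximal 1 Mb, and the 3 clusters with the highest score in each library. It applied because genes could not be placed. The gene table used here is of release 6, and coordinates of both releases were not mixed. The planned lists of pericentric, chromosome 4, H3K9 methylation, Polycomb target, housekeeping and clustered-family genes were therefore not tested, and no gene is named. Alternatives were a stricter score limit (the list's median), joining clusters within 1 kb, a minimum length of 1 kb, an overlap of 50%, other proximal windows (0.5 and 2 Mb), other sets of sequences, each library alone and the series-wide list.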

Results

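H3K9me3, the histone mark typical of constitutive heterochromatin, was mapped by ChIP-seq in wild-type Drosophila melanogaster embryos 14 to 16 h old. The group comprised 2 ChIP libraries, each with its own input library, and an additional list for the whole series. Replicate 1 held 3395 clusters covering 21.5 Mb and replicate 2 held 3404 clusters covering 20.7 Mb. These spans amounted to 15.4% and 14.8% of the 13 sequences with clusters. The median cluster was 2944 bp long in replicate 1 and 2969 bp in replicate 2, and the longest reached 92329 bp and 87025 bp. The number of reads behind the clusters is unknown. All positions are on FlyBase release 5. With a single condition and stage, the comparisons the design allows are between the 2 libraries, between each library and the series-wide list, and between parts of the genome.

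The first comparison asked where in the genome the mark lay. It covered most of the separately assembled heterochromatic scaffolds, of the small chromosome 4 and of the unplaced sequence U, and little of the 5 large chromosome arms. The 6 heterochromatic scaffolds, 9.28 Mb in all, were covered to 72.1% ± 1.52 (SD, n = 2). The scaffold of 3L was covered most widely, at 80.3% ± 1.62 (SD, n = 2), followed by 3R at 73.7% ± 1.45, 2R at 69.3% ± 1.34 and 2L at 65.4% ± 2.04. With only clusters at or above the list's median score, the last 2 changed places, at 57.5% for 2R and 61.1% for 2L. The Y scaffold was covered to 58.5% ± 2.49 and the X scaffold to 28.8% ± 1.42 (SD, n = 2 each). The X scaffold is 0.204 Mb long, and its share rests on 7 clusters in replicate 1 and 6 in replicate 2. Unplaced sequence was covered to 64.4% ± 1.44. The 5 arms together, 119 Mb, were covered to 5.94% ± 0.184 (SD, n = 2). Among them the share fell from 8.88% ± 0.168 on 2R and 7.61% ± 0.172 on 3L to 7.13% ± 0.347 on X, 5.47% ± 0.137 on 2L and 1.66% ± 0.116 on 3R. The place of X depended on the clusters kept: with only those at or above the list's median score it fell to 1.79%, below 2L at 3.08%, and in the series-wide list it reached 10.0%, above 3L at 9.12%. On 3R the share was 0.241% with that score limit and 2.63% in the series-wide list. Each heterochromatic scaffold exceeded each arm by far more than the SD of the 2 libraries. Sequences are single items, so no test across them was made. In the per-library lists, the scaffolds held 31.6% and 31.8% of all covered bases, unplaced sequence 30.6% and 30.7%, and the arms 33.7% and 33.3%.

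**Figure D1:**
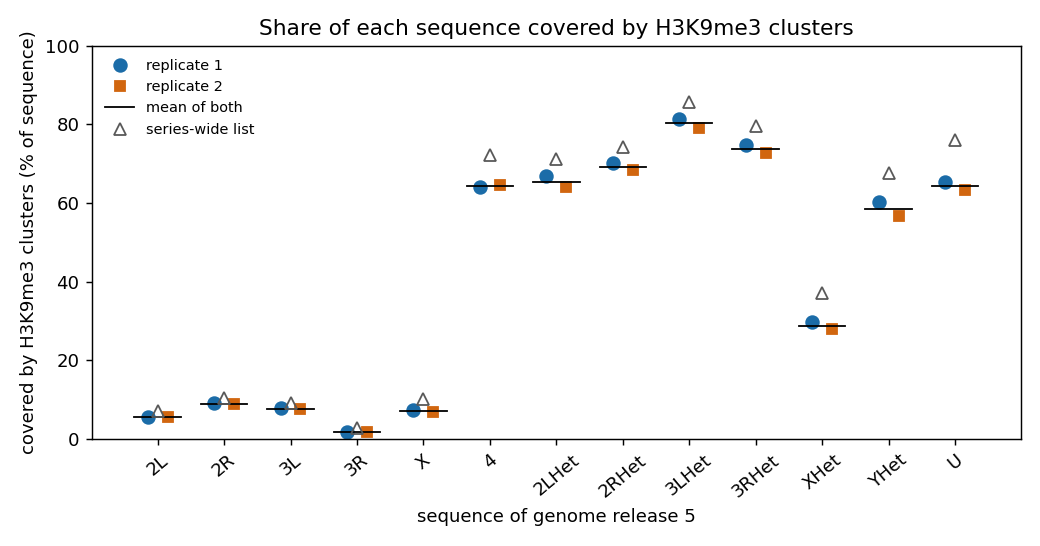
Percentage of each release 5 sequence covered by H3K9me3 clusters, for replicate 1 (circles), replicate 2 (squares), their mean (bars) and the series-wide list (open triangles). The 5 arms lie between 1.66% and 8.88% (means), chromosome 4 at 64.3%, and the heterochromatic scaffolds between 28.8% and 80.3%.

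Within the arm sequences, coverage was denser at the end facing the centromere, the side of pericentric heterochromatin. By amount, the larger part of arm coverage lay elsewhere. The proximal 1 Mb windows held 12.5% and 12.7% of all covered bases in the per-library lists, and the rest of the arms 21.2% and 20.7%. The centromere-proximal 1 Mb of 2R was covered to 86.2% ± 0.603, that of 3L to 84.6% ± 1.57 and that of 2L to 67.1% ± 0.207 (SD, n = 2 each). The remainder of these arms was covered to 5.05% ± 0.146, 4.34% ± 0.112 and 2.67% ± 0.134, which makes the proximal share 17.1-fold, 19.5-fold and 25.1-fold higher. Among clusters at or above the list's median score these folds were 28.5, 38.6 and 76.5, and in the series-wide list 14.1, 15.8 and 17.9. On X the proximal 1 Mb was covered to 22.0% ± 1.13 against 6.44% ± 0.310 elsewhere, and on 3R to 5.85% ± 0.406 against 1.51% ± 0.105. The proximal share was higher in 5 of 5 arms, by 49.1 percentage points on average ± 36.6 (SD over arms). The exact two-sided permutation test over the arms gave p = 0.063, the smallest value that 5 arms allow. Within single arms, circular shifts gave adjusted p = 0.012 for 2L, 2R, 3L and 3R and adjusted p = 0.025 for X (permutation by shifts, one-sided, 5 tests). With a window of 0.5 Mb the difference on X turned to -2.85 points, since the windows nearest the proximal end of the X arm sequence were little covered.

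Counted from the proximal end of each arm sequence, widely covered stretches had different lengths on the 5 arms. The heterochromatic scaffolds are separate sequences, of 3.29 Mb for 2R, 2.56 Mb for 3L, 2.52 Mb for 3R and 0.369 Mb for 2L. The lengths below therefore also depend on where each arm sequence ends, and do not give the full extent of the marked domains. On 2R the second and the third Mb from the proximal end were still covered to 48.8% ± 1.24 and 14.7% ± 0.196, and the next to 3.61% ± 0.0896 (SD, n = 2 each). On 3L the second Mb was covered to 47.0% ± 0.247 and the third to 2.36% ± 0.442. On 2L coverage fell to 5.31% ± 0.0144 in the second Mb and was 8.61% ± 0.179 in the third. Counted in windows of 100 kb from the proximal end, windows covered to at least 50% followed each other without interruption over 1.6 Mb on 2R, 1.5 Mb on 3L and 0.8 Mb on 2L. No window of 3R reached this level. On X, 2 of 224 windows did, and they lay between 0.6 and 0.8 Mb from the proximal end.

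The outermost 100 kb at the telomeric ends differed between arms as well. This stretch was covered to 24.5% ± 0.457 on 3L and 19.3% ± 0.725 on X. It was covered to 3.31% ± 1.29 on 2L, 0.986% ± 1.39 on 3R and 0.791% ± 1.12 on 2R (SD, n = 2 each), where the SD is of the order of the value. The 3L and X ends thus exceeded the other arms by more than the spread between the libraries.

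**Figure D2:**
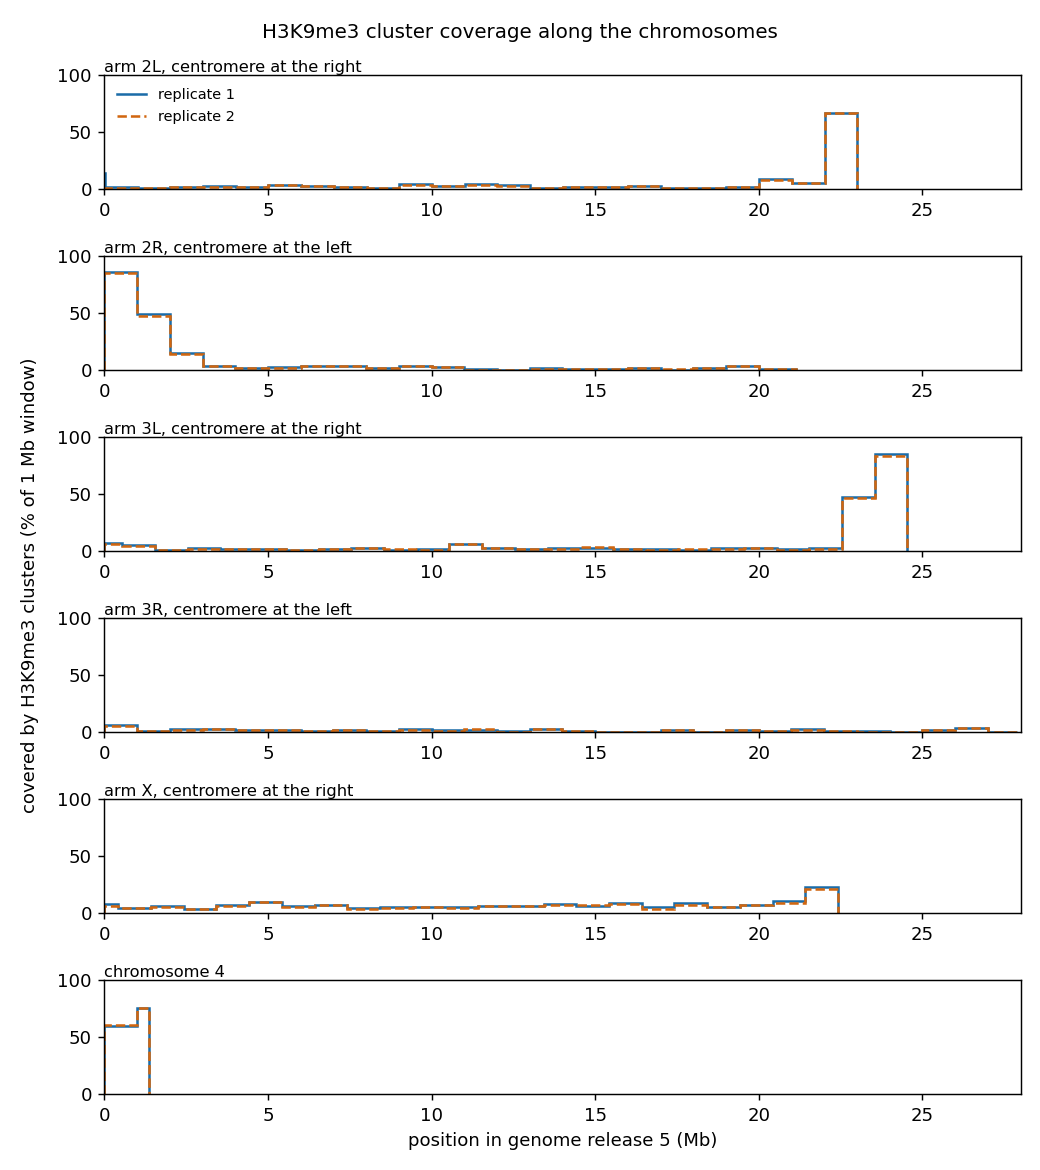
Percentage of each 1 Mb window covered by H3K9me3 clusters along the 5 arms and chromosome 4 (release 5 positions), for replicate 1 (solid) and replicate 2 (dashed); windows are counted from the centromere-proximal end, so the outermost one is shorter. Coverage peaks in the proximal 1 Mb of 2R (86.2%), 3L (84.6%) and 2L (67.1%), is lower there on X (22.0%) and lowest on 3R (5.85%).

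Chromosome 4, known as a small and largely heterochromatic chromosome that nevertheless carries active genes, was covered to 64.3% ± 0.481 (SD, n = 2). The arms outside their proximal 1 Mb lay 60.3 percentage points lower on average, with an SD of 0.642 between the libraries. The difference was 9.99-fold against X, the most widely covered arm outside that window, and 42.6-fold against 3R, the least. Among clusters at or above the list's median score 2R was the most widely covered arm outside that window. Chromosome 4 then exceeded 2R 17.8-fold, X 46.4-fold and 3R, of which only 0.212% was still covered there, 228-fold. In the series-wide list these folds were lower, at 11.2 against 2R, 7.79 against X and 30.4 against 3R. Coverage of chromosome 4 was interrupted: 100 regions, of median length 6154 bp, were covered in both libraries, and 100 stretches were uncovered in both. Stretches covered in 1 library alone belong to neither kind, so the equal counts do not mean that these alternated. Of the uncovered stretches 14 were at least 10 kb long. Coverage reached 60.4% ± 0.727 in the first Mb of chromosome 4 and 75.7% ± 0.221 in the remainder.

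Clusters also differed in length and in the authors' score, whose scale is not stated. Clusters on the heterochromatic scaffolds had a median length of 7451 bp ± 182, those in the proximal 1 Mb of the arms 6258 bp ± 334 and those on chromosome 4 5382 bp ± 800 (SD, n = 2). Elsewhere on the arms the median was 2090 bp ± 30.8. Median scores ran in a similar order, at 2.44 ± 0.06 on the scaffolds, 2.15 ± 0.04 in the proximal windows, 1.72 ± 0.08 on chromosome 4 and 1.06 ± 0.002 on the rest of the arms. Unplaced sequence had shorter clusters, of 3719 bp ± 123, with the highest median score, 2.76 ± 0.03. In the series-wide list the order of lengths differed, with medians of 4947 bp on unplaced sequence, 4147 bp in the proximal windows and 3116 bp on chromosome 4, whose median score there was 0.837 against 0.742 on the rest of the arms. The 3 clusters with the highest score in each library also lay on unplaced sequence. In replicate 1 they were at positions 6300155 to 6302528 (score 5.79), 4559642 to 4563374 (5.72) and 2183360 to 2186022 (5.42), with scores of 3.93, 3.33 and 4.66 for the overlapping clusters of replicate 2. In replicate 2 they were at 9774097 to 9776258 and 8254992 to 8257235 (5.31 each) and at 9799667 to 9801004 (5.19), with scores of 4.65, 4.58 and 3.46 for those of replicate 1.

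The longest region covered in both libraries lay within 1.06 Mb of the proximal end on 4 of the 5 arms. The longest was on 2R, at 403300 to 483505 (80206 bp), with a score of 3.23 in replicate 1 and 3.36 in replicate 2. On 2L it was at 22506784 to 22566783 (60000 bp, scores 2.86 and 2.82) and on X at 21765279 to 21811205 (45927 bp, scores 2.91 and 2.80). On 3L it lay just outside the proximal 1 Mb, at 23438138 to 23483984 (45847 bp, scores 3.25 and 3.15). On 3R the longest region was far from the centromere, at 17934841 to 17945445 (10605 bp, scores 1.95 and 2.00). On chromosome 4 it spanned 359150 to 395757 (36608 bp, scores 2.89 and 3.11).

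Outside the proximal 1 Mb, long regions were few. Regions of at least 10 kb covered in both libraries numbered 16 on 2R, 14 on 3L, 3 on 2L, 2 on X and 1 on 3R. The 3 longest on 2R lay between 1.01 and 1.43 Mb from the end of the arm, at 1434136 to 1491951 (57816 bp), 1013472 to 1057290 (43819 bp) and 1335065 to 1373167 (38103 bp). Those on 3L were the longest region already given, 23031230 to 23065753 (34524 bp) and 23287484 to 23321341 (33858 bp), all within 1.48 Mb of the end. On 2L a pair of regions lay 2.81 and 2.89 Mb from the end, at 20172585 to 20198524 (25940 bp, scores 2.98 and 3.21) and 20099485 to 20121297 (21813 bp, scores 2.88 and 2.91). The third on 2L was in the middle of the arm, at 11318471 to 11328690 (10220 bp, scores 2.07 and 2.25). On X they were at 20839467 to 20855181 (15715 bp), 6446525 to 6457598 (11074 bp) and 17842192 to 17851995 (9804 bp). On 3R the second and the third were at 11416307 to 11425984 (9678 bp, scores 1.33 and 1.54) and 21219569 to 21228258 (8690 bp, scores 2.46 and 2.56).

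The second comparison asked how far the 2 libraries gave the same regions. Their covered bases had a Jaccard index of 0.855, against 0.315 on average and 0.377 at most over 1000 circular shifts (permutation by shifts, one-sided p = 0.001, the smallest they can give). Of the replicate 1 clusters 85.0% overlapped replicate 2 (2885 of 3395, 95% interval 83.7 to 86.2%), and of the replicate 2 clusters 89.8% overlapped replicate 1 (3058 of 3404, 88.8 to 90.8%). Shifted lists gave 49.9% and 51.9%. The Jaccard index was 0.933 on the heterochromatic scaffolds, 0.924 in the proximal windows, 0.890 on chromosome 4, 0.857 on unplaced sequence and 0.704 on the rest of the arms. Shifted lists averaged 0.575, 0.584, 0.472, 0.475 and 0.024 in the same order, so wide coverage alone gives much of the overlap outside the rest of the arms. On chromosome 4 so much is covered that the share of overlapping clusters, 87.4% for replicate 1, was close to the 84.8% of shifted lists (permutation by shifts, p = 0.256). Clusters present in 1 library alone, 510 in replicate 1 and 346 in replicate 2, had median lengths of 1661 bp and 1628 bp and median scores of 0.93 and 0.88. The clusters found in both had medians of 3585 bp and 3383 bp with scores of 2.16 and 2.10. Of those in 1 library alone 67.6% and 71.1% lay on the arms outside the proximal 1 Mb. That part held 1421 of all 3395 clusters and 1344 of all 3404. Its clusters had median lengths of 2112 bp and 2068.5 bp and a median score of 1.06 in both libraries. Part of the contrast may thus come from where these clusters lie.

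Scores of clusters that overlapped one to one were ranked alike in both libraries. Over 2182 such pairs Spearman's rho was 0.947 (95% bootstrap interval 0.941 to 0.951). Within classes rho was 0.958 on chromosome 4 (57 pairs), 0.920 in the proximal windows (147 pairs), 0.920 on the scaffolds (311 pairs), 0.865 on the rest of the arms (985 pairs) and 0.799 on unplaced sequence (682 pairs). These are relations across clusters, which are not independent replicates.

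**Figure D3:**
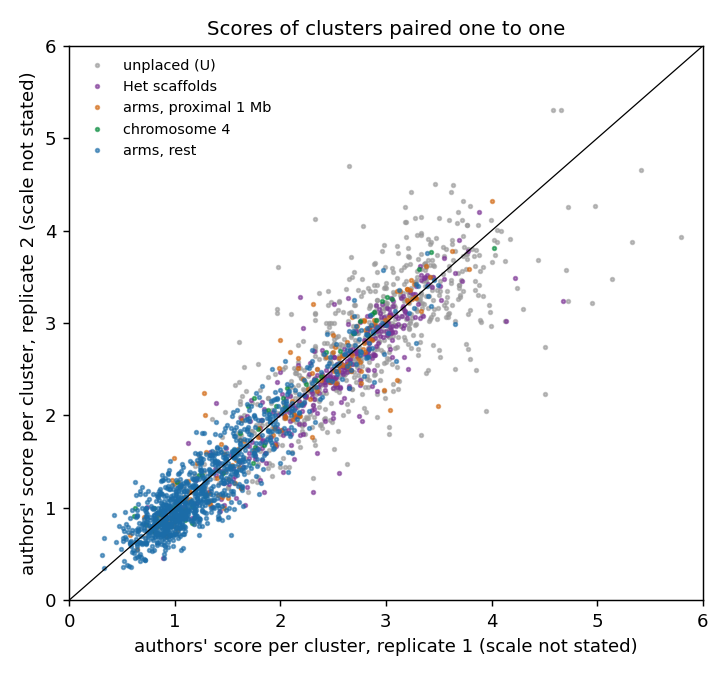
Authors' score (scale not stated) of each of 2182 clusters paired one to one, in replicate 1 (horizontal axis) and replicate 2 (vertical axis), coloured by part of the genome; the line marks equal scores. Arm clusters outside the proximal 1 Mb sit low (medians of 1.18 and 1.14 over the pairs) and clusters on unplaced sequence high (2.83 and 2.81).

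The third comparison set the series-wide list against the libraries. It held 3941 clusters covering 24.9 Mb, and 99.9997% of the bases covered in both libraries lay within it. Of its clusters 61.1% (95% interval 59.5 to 62.6%) overlapped both libraries, 18.8% (17.6 to 20.1%) overlapped 1 and 20.1% (18.9 to 21.4%) overlapped neither. Counted base by base, 78.1% of its bases were covered in both libraries, 12.7% in 1 and 9.19% in neither. The last share also counts uncovered parts of clusters that do overlap a library. The 794 clusters found in neither library were short, with a median of 1299 bp. On the arms outside the proximal 1 Mb lay 68.5% of them, against 73.7% of the clusters found in 1 library and 42.9% of those found in both. In this list chromosome 4 was covered to 72.2% and the scaffolds to 77.7%. By its label the list stands for the set of replicates, so it is no independent sample.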

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

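Direction and side of the threshold held for the overlap of the libraries (Jaccard index 0.704 to 0.861, p = 0.001 by permutation of positions under each alternative) and for the mean proximal excess (34.7 to 52.5 percentage points). The test over 5 arms cannot pass 0.05, so its p of 0.063 (0.12 with a 0.5 Mb window, exact permutation) says nothing about stability. Of the 40 alternatives for single arms 39 kept their call, but these include the minimum length, which removed no cluster. That of X with a 0.5 Mb window reversed, to -2.85 points (adjusted p = 0.775 by permutation of positions), because the covered windows of X lie further in. Keeping only clusters with a score at or above the list's median lowered the covered share to 11.5% of all sequences, 3.13% of the arms and 63.7% of the heterochromatic scaffolds, and the lead of chromosome 4 to 47.1 points; it gave a median length of 5535 bp, by construction a higher median score (2.76), and a rho of 0.759 between libraries. The series-wide list gave 17.8%, 7.62% and 77.7% for these shares, a lead of chromosome 4 of 66.6 points, a median length of 2484 bp and a median score of 1.34. That lead was 61.3 points with clusters within 1 kb joined, 58.2 against whole arms and 61.2 against arms outside their proximal 2 Mb. Requiring 50% overlap lowered the share of series-wide clusters found in both libraries to 58.8%. A score limit can only lower covered shares, and a stricter overlap rule can only lower the share found in both, so those directions were fixed in advance. The score limit also narrows the range of the scores that are ranked, which can by itself lower rho. The cause of the other shifts was not tested further. For single sequences, 28 of 78 alternatives moved the covered share by over 1 SD. The 78 include the minimum length and leaving out either library, which could not move it so far. The higher score limit and the series-wide list moved it on every sequence, and joining within 1 kb moved it on chromosome 4 and unplaced sequence. The folds between parts of the genome, whose alternatives were added after the data were seen, moved by over 1 SD in all 10 cases for the proximal windows and all 10 for chromosome 4. With the higher score limit they rose, to between 4.75 and 76.5 for the proximal windows and between 17.8 and 228 for chromosome 4. In the series-wide list those of chromosome 4 fell, to between 7.79 and 30.4. The proximal folds fell there to between 2.88 and 17.9, except that of 3R, which rose from 3.88 to 4.04. Leaving out either library cannot move a mean of 2 by over 1 SD and tests nothing for these shares, while the proximal excess kept its call in each of the 5 arms with either library alone. The minimum length of 1 kb removed no cluster and tests nothing. Genes under clusters were not run, for want of a release 5 annotation here. No paired analysis was possible because the input libraries, which share the replicate numbers, have no values used here. Unknown depth limits what the absence of a cluster can show.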

Other observations

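Outside pericentric regions, X carried many more small clusters than the autosomal arms. This pattern, its alternatives and the tests of this part were chosen after the results were seen, except those of the score limit on X and of the arm scores of clusters only in the series-wide list against those found in both libraries, which were written before their results were seen. Outside the proximal 1 Mb X held 24.7 clusters per Mb ± 1.02, against 9.22 ± 0.351 on 2L, 2R, 3L and 3R together (SD, n = 2), a ratio of 2.68 ± 0.009. The next highest arm, 2R, held 11.2 ± 0.456 and the lowest, 3R, 5.91 ± 0.631. The clusters were of like length, with medians of 2089 bp ± 26.9 on X and 2092 bp ± 38.2 on the autosomal arms, and their median scores were 1.11 ± 0.03 and 1.02 ± 0.00085. In 1 Mb windows over 3 Mb from the proximal end, the covered share had a median of 6.01% on X (19 windows, 3.62 to 9.68%) and 1.90% on the autosomal arms (83 windows, 0.261 to 6.15%), and 1 autosomal window exceeded the X median (permutation test over windows, two-sided p = 2e-05, the smallest it can give). Windows of 1 chromosome are not independent, and 1 X against 4 autosomal arms cannot give an exact permutation p under 0.2.

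Chromosome 4 was the other place with a mixed pattern, this time of gaps within coverage. Its longest stretch uncovered in both libraries ran from 400838 to 437286 (36449 bp), shortly after its longest covered region, which ended at 395757. The next were 522152 to 550798 (28647 bp), 646119 to 667870 (21752 bp) and 751156 to 772278 (21123 bp). These stretches were chosen after their values were seen.

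The higher density on X was not confined to the lower-scoring arm clusters. At or above the median score of arm clusters the ratio was 3.22 (2.09 to 6.20 over single autosomal arms and libraries). The authors' threshold is not stated, so this limit cannot tell how many clusters on X are weak calls. Most scored below the median of the whole list: at or above it X held 2.05 clusters per Mb and the autosomal arms 1.38, outside the proximal 1 Mb. Calls that do not recur and domains near the X centromere do not account for the density of clusters on X. The ratio was 2.76 for regions per Mb covered in both libraries (2.14 to 4.56 over single arms). Outside the proximal 3 Mb it was 3.05 for clusters per Mb. For the median covered share of windows over 3 Mb away, another measure, it was 3.16 (2.72 to 3.83 over single arms). At the stricter median of the whole list the ratio of clusters per Mb was 1.49 and that of the covered share 0.788 outside the proximal 1 Mb, but 3.51 ± 0.153 and 3.11 ± 0.431 (SD, n = 2) outside the proximal 3 Mb, which leaves out the long domains of 2R and 3L. Whether the copy number of X in male embryos affected the calls, and whether repeats or genes specific to X did, was not tested, since neither input values nor annotation were used; the design holds no groups, so no biological explanation was tested.

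The low coverage of the proximal 1 Mb of 3R, 5.85%, stood apart from 2L, 2R and 3L. Fewer calls along the whole of 3R are not the whole difference from those arms, since the ratio of proximal to remaining share was 3.88 on 3R against 17.1 to 25.1 there, while keeping fewer clusters by score raised this ratio on each of the 5 arms. X was left out of that range after its value was seen; its ratio was 3.42 with all clusters but 17.2 among those at or above the list's median score, where that of 3R was 4.75 and those of 2L, 2R and 3L were 28.5 to 76.5. A candidate explanation is that the 3R sequence of release 5 ends before the heavily marked part. The separate heterochromatic scaffold of 3R was covered to 73.7%, within the 65.4 to 80.3% of the scaffolds of 2L, 2R and 3L, as that explanation needs. This cannot decide the question, since 2L, 2R and 3L had such scaffolds together with widely covered proximal windows. The scaffold of X, left out of that range, was covered to 28.8%, but it is 0.204 Mb long and held only 7 and 6 clusters in the libraries.

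The 794 clusters that the series-wide list held and neither library did may have come from a different minimum length or from weaker enrichment. Of them 50.1% (398) were shorter than the shortest per-library cluster, and whether a length limit kept those out was not tested. The others passed that length in the series-wide list, those on the arms outside the proximal 1 Mb with a median of 1606 bp. A call in 1 library can be shorter than the series-wide cluster at its site, so these lengths cannot exclude a length limit for the others. Of the longer ones, the 269 on the arms outside the proximal 1 Mb had a median score of 0.555, below the lower quartile (0.796) and median (1.07) of such clusters found in both libraries, as weaker enrichment needs, but those found in 1 library had a median of 0.570, so a low score does not set apart the clusters that neither library has. On the heterochromatic scaffolds and unplaced sequence, the clusters in neither library of that length had median scores of 1.87 (36 clusters) and 2.35 (60), above the 1.23 and 1.80 of those found in 1 and close to the lower quartiles of 1.99 and 2.29 of those found in both, so weaker enrichment stays open for these parts. Whether reads were pooled for the series-wide list stays open.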
